A study of Mus musculus with 2 samples.

How the data were processed

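Total RNA of the nucleoplasmic fraction was depleted of ribosomal RNA and sequenced from lipid A-treated mouse macrophages, per the labels, which elsewhere call the fraction nuclear. The labels give a size range of 250 to 400 without a unit, biological replicate numbers 1 and 2, and starting amounts of 500 ng and 1 µg. For each library 3 quantification tables were used. The deposited expected counts per gene and per transcript were made from alignments to the transcriptome of mm10 with the GENCODE M21 annotation, per the deposited file notes. The deposited TPM values in the same tables are scaled to a fixed total over all their entries, and a posterior mean TPM with its interval accompanies them, per the file headers. The third table holds estimated counts and TPM per transcript made directly from the reads, per the deposited file notes. The programs and the strand setting are not given in the sources used here. The columns of the first 2 tables have the layout RSEM writes and those of the third the layout kallisto writes, and the text names them so.

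All 55536 genes of the reference annotation (GENCODE M21, GRCm38) were found in the gene tables, so gene names, biotypes and coordinates were taken from it. The 26248 entries with numeric identifiers of 61 to 259 bases, which the reference does not name, and the spike-in entries were kept out of gene lists and tests. The phiX174 entry held 0.281% of expected counts in replicate 1 (95% Wilson interval 0.279 to 0.284%) and 0.0639% in replicate 2 (0.0628 to 0.0650%). The numeric identifiers held 50 and 30 counts. The libraries totalled 20196408 and 19588980 expected counts in the gene tables and 34774610 and 27988909 estimated counts in the kallisto-layout tables. Intervals and limits of counts cover counting error only, and spreads measure only these samples. The interval for the shift of ribosomal protein mRNAs covers variation among list members instead.

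Before the data were examined, 25 gene lists with 366 genes, 6 comparisons between lists, the tests and the rule for named genes were fixed. The rule named the 3 members of each list with the highest mean TPM, 14 preset genes, the 20 genes with the highest mean TPM, the 10 genes with the largest ratio between replicates in each direction among those with at least 100 expected counts in each library, and the 5 highest retained-intron shares. A gene that the rule names is not reported here. Rn7sl1, Rn7sl2 and Snord3a have no entry of that name in the annotation. For Aldoa, Ddit3 and Rmrp, each with more than 1 entry, the entry with the most counts was used.

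Each comparison between lists was the difference of the medians of log2(TPM + 1) in each library, given as the mean and SD of 2 libraries. Its percentile was taken among 10000 pairs of random lists of the same sizes from genes with an expected count of at least 10 in both libraries. The pseudocount of 1 understates differences among low genes. For the ratio between replicates, the median log2 ratio of each list with at least 5 detected members was placed among 10000 random lists matched on mean expression in 20 bins. The interval of the shift of ribosomal protein mRNAs came from 10000 resamplings of the members. No p-value was computed across genes. Dispersion was estimated with edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers, with TMM factors, filterByExpr and an intercept only. DESeq2 1.42.0 size factors were an alternative. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the rest.

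The list procedure was tested on simulated data with 200 genes changed 2-fold. Over 14812 genes, all 19 lists of 10 changed genes lay above the middle 95% of matched lists, and 6 of 200 lists of unchanged genes lay outside it. Genes were drawn independently, with the same effective length in both libraries. The rate for unchanged lists therefore need not hold for real lists, whose members can vary together. The median shift of the changed lists relative to matched lists was 0.76 log2 units, below the simulated change. For the replicate variation, simulated coefficients of 0.1, 0.2 and 0.4 were recovered as 0.116, 0.204 and 0.391 over 14845, 14746 and 14402 genes, so the lowest was overstated.

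Several steps can affect the values. TPM divides by an effective length, which is very small for RNAs shorter than the fragments, so a few reads on such an RNA give a high TPM, and shares of RNA classes and retained-intron shares are given both by TPM and by counts. The tables count reads on annotated transcripts, so an intron counts only where a transcript that retains it is annotated. Without a stated strand setting, reads of overlapping antisense genes cannot be told apart. Alternatives were the posterior mean TPM, the kallisto-layout table, TPM rescaled to protein-coding and listed genes, TMM-normalised CPM, a pseudocount of 0.1, filters on counts, and leaving out each replicate. The kallisto-layout table rescaled to protein-coding genes, its counts as shares, the retained-intron shares by counts, the filter on the mean count, the correction for GC content, length and level, the percentiles of list comparisons under alternatives and the count of lists above random lists were chosen after seeing the data. Signal tracks and alignments named in the deposited notes were not used here.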

Results

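Ribosomal-RNA-depleted total RNA of the nucleoplasm was measured in bone-marrow-derived macrophages, phagocytes grown in culture from marrow progenitors, of C57BL/6J mice. The cells were exposed to 100 ng/ml lipid A, the part of bacterial lipopolysaccharide that TLR4 recognises, for 12 h. After a washout of 12 h they received the same dose again, for 25 min. The 2 libraries formed 1 group of 2 biological replicates, and no untreated, singly stimulated or cytoplasmic sample was analysed here. Every comparison below is therefore between gene lists within a library or between the 2 replicates, and none gives a response to lipid A. Both libraries carried the same donor entry, so the spread between them may be technical. Replicate 1 was started from 500 ng and replicate 2 from 1 µg of RNA, so replicate and starting amount could not be told apart.

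Replicate 1 held 20196408 and replicate 2 held 19588980 expected counts, and 14596 genes had an expected count of at least 10 in each. Across these genes the replicates had a Pearson correlation of 0.970 and a Spearman correlation of 0.967 on the log2(TPM + 1) scale, where genes are not independent replicates. The counts of the 2 libraries differed by more than sampling noise, with a chi-square per degree of freedom of 85.9, so the files do not hold repeat copies of 1 library. The test does not show whether the cultures were separate. The biological coefficient of variation from edgeR was 0.246. The median detected gene lay at a log2 ratio of -0.21 for replicate 2 over replicate 1 on the TPM scale and at 0.00 after TMM normalisation. Shifts of gene lists between replicates are given below relative to matched genes. Ratios of single genes, SDs of TPM and the plotted list medians are not adjusted in this way. A small SD of TPM therefore need not mean close replication. Ctsd, for example, had 1883 ± 5.54 TPM (SD, n = 2), but 3309 TMM-normalised CPM in replicate 1 and 4016 in replicate 2. A count of 0 allows a share of up to 1.49e-05% of replicate 1 and 1.53e-05% of replicate 2, and these limits cover counting error only.

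Short structural RNAs made up much of the nucleoplasmic RNA by TPM. Rn7sk, the 7SK RNA that holds the elongation factor P-TEFb inactive (chromosome 9, 78175303 to 78175633), had 214020 ± 10783 TPM (SD, n = 2), the highest of all genes in the RSEM-layout values. In the kallisto-layout values Gm12895 exceeded it in replicate 1 (109803 against 89412 TPM) and Gm24270 in replicate 2 (251057 against 24798 TPM). Rpph1, the RNA of ribonuclease P, had 34593 ± 708 TPM, and Gm22513, an annotated small nuclear RNA, had 22627 ± 415 TPM. Expected counts in replicates 1 and 2 were 71699 and 101193 for Rpph1 and 2481 and 6883 for Gm22513. The small SDs of TPM of these short RNAs therefore do not show close replication. The pair of gene models of Rmrp, the RNA of ribonuclease MRP, overlap and share reads. Summed, they had 46706 TPM in replicate 1 and 76922 TPM in replicate 2. The near-identical 7SL genes Rn7s1 and Rn7s2, the RNA of the signal recognition particle, were given equal values of 16874 TPM in replicate 1 and 45020 TPM in replicate 2, and each single value is uncertain. The 7 annotated members of the list of small nuclear and ribonucleoprotein RNAs took 30.3% of TPM in replicate 1 and 29.7% in replicate 2, but 3.81 ± 0.963% of expected counts (SD, n = 2). All snRNA, snoRNA and scaRNA genes took 19.7 ± 3.91% of TPM and 0.384 ± 0.213% of counts. Protein-coding genes outside the mitochondrial genome took 28.4 ± 1.52% of TPM and 74.2 ± 0.746% of counts. In the kallisto-layout table these 3 shares of TPM were 11.9%, 3.97% and 22.8% in replicate 1 and 3.59%, 1.66% and 5.27% in replicate 2.

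**Figure D1:**
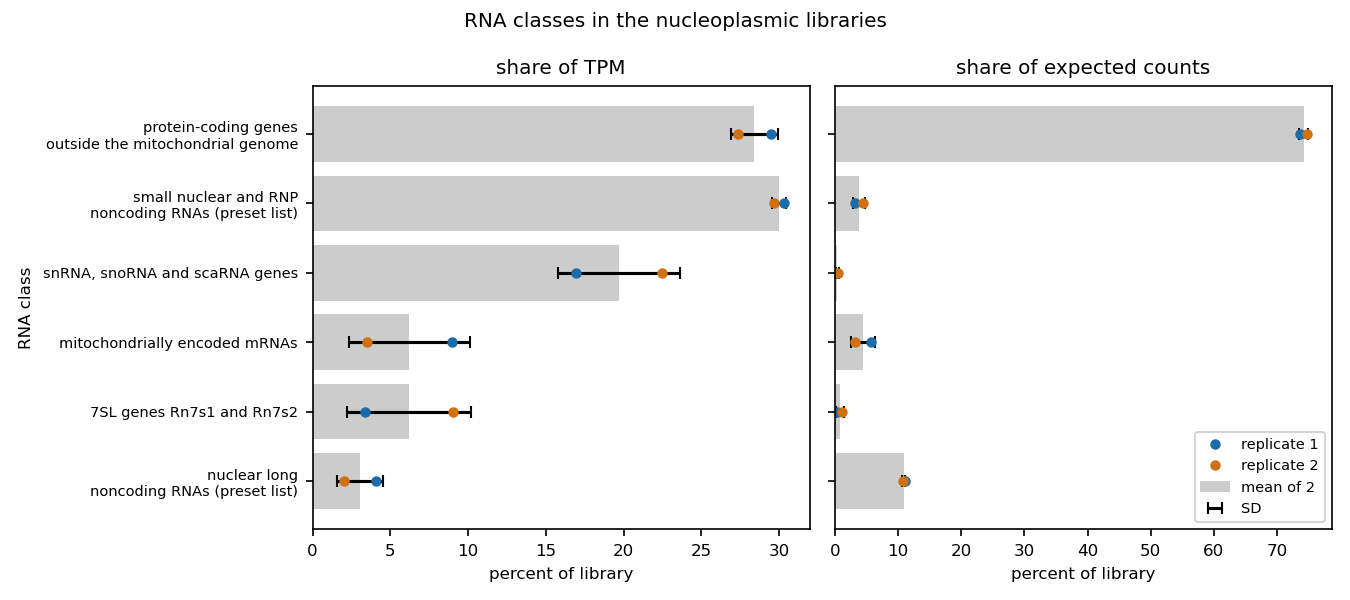
Share of each library in 6 RNA classes, in percent of TPM (left) and of expected counts (right), with bars for the mean of 2 libraries, whiskers for the SD and points for each replicate; classes are not exclusive. Protein-coding genes outside the mitochondrial genome hold 28.4% of TPM and 74.2% of counts.

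Malat1, a long noncoding RNA of nuclear speckles (chromosome 19, 5795690 to 5802672), took 10.2 ± 0.217% of expected counts, and Neat1, the scaffold of paraspeckles (chromosome 19, 5824708 to 5845478), took 0.557% in each library. Malat1 had 39254 TPM in replicate 1 and 18418 TPM in replicate 2. Most of that gap lay in the annotated 485-base transcript Malat1-203, with 23619 and 4763 TPM. The 6983-base transcript Malat1-201 had 14567 and 13050 TPM, 13808 ± 1073 TPM on average (SD, n = 2). Neat1 had 1092 ± 73.8 TPM. Its 3004-base transcript had 909 ± 112 TPM and its 20771-base transcript 134 ± 39.0 TPM. Mir22hg (94.5 ± 2.88 TPM) was the third of the nuclear long noncoding RNA list, of which 13 of 16 members reached 1 TPM in both libraries.

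Nuclear long noncoding RNAs were compared with ribosomal protein mRNAs, cytoplasmic messages of translation. With no cytoplasmic sample analysed here, the comparison cannot show how free of cytoplasm the fraction was. By the list median the long noncoding RNAs were lower, with a difference of -2.06 ± 0.41 log2 units (SD, n = 2), at percentile 0.15 among 10000 pairs of random lists. The ribosomal protein list had a median of 39.3 ± 1.66 TPM, led by Rps24 (192 ± 72.7 TPM), Rps9 (104 ± 25.1 TPM) and Rpl3 (79.4 ± 8.30 TPM). The difference turned to 0.63 on TMM-normalised CPM, which are not divided by length, at percentile 74.5. It was -0.42 over detected members (percentile 29.7), -0.60 in the kallisto-layout table (13.4) and -0.70 in that table rescaled to protein-coding genes (16.5), so the call ended under each of these. Mitochondrially encoded mRNAs had a median of 4139 TPM in replicate 1 and 1839 TPM in replicate 2, led by mt-Atp8 (18794 ± 17678 TPM), mt-Co1 (15683 ± 6532 TPM) and mt-Nd6 (6957 ± 2911 TPM). By expected counts mt-Atp8 did not lead, with 11786 and 5201 against 534232 and 327217 for mt-Co1.

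Macrophage identity genes stood far above the markers of other cell types. All 28 were above 1 TPM in both libraries, with a list median of 186 ± 26.2 TPM (SD, n = 2). Gpnmb, a glycoprotein of phagocytes, had 2071 ± 43.5 TPM. The lysosomal proteases Ctsb and Ctsd had 1884 ± 217 and 1883 ± 5.54 TPM, and Ctsd overlaps Gm49369 on the same strand, so reads can be split between them. Lymphocyte markers had a median of 0.0600 TPM in replicate 1 and 0.0400 TPM in replicate 2, and Cd4 (26.2 ± 3.62 TPM) was the only 1 of 14 above 1 TPM in both libraries. The difference between the lists was 7.47 ± 0.22 log2 units, above all 10000 random pairs. Random lists held detected genes only, so undetected lymphocyte markers contribute to that rank. The difference was 4.64 when only members with at least 10 counts in both libraries were kept, which left the 2 lymphocyte markers Cd4 and Cd79b.

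List medians of the markers of other cell types a marrow culture could hold were below 1 TPM. Neutrophil markers had a median of 0.0900 ± 0.127 TPM, with Csf3r, the receptor for the growth factor G-CSF, at 87.3 ± 1.89 TPM, Mmp8 at 1.60 ± 0.488 TPM and Ltf at 0.555 ± 0.191 TPM. Ly6g, Cxcr2, Mpo, Elane and Retnlg had 0 counts in both libraries, and were singled out after their values were seen. Dendritic cell markers had a median of 0.345 ± 0.00707 TPM. Their highest member, Bst2, is also induced by interferon and had 112 TPM in replicate 1 and 302 TPM in replicate 2, and Ccr7 followed at 1.29 ± 0.156 TPM. Erythroid markers had a median of 0.0175 ± 0.0247 TPM and mast cell and basophil markers of 0.0400 TPM, with Alas2 at 2.24 ± 1.01 TPM and Kit at 1.24 ± 0.163 TPM. Stromal and endothelial markers had a median of 0.0225 ± 0.00354 TPM, with Kdr, a receptor for the growth factor VEGF, at 9.67 TPM in replicate 1 and 18.3 TPM in replicate 2.

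Early cytokines and chemokines were abundant in the nucleoplasm of the restimulated cells, while most secondary-response genes were at low levels. The early list had a median of 69.6 ± 31.1 TPM (SD, n = 2), and 11 of its 14 members reached 1 TPM in both libraries. Tnf, the cytokine TNF (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007), had 448 ± 10.9 TPM. The chemokines Ccl3 and Cxcl2 (chromosome 5, 90903871 to 90905938) had 242 ± 21.4 and 235 ± 135 TPM, and Il1b (chromosome 2, 129364570 to 129371139) had 99.4 ± 59.3 TPM. The secondary-response list had a median of 1.66 ± 0.219 TPM. Il6 (chromosome 5, 30013114 to 30019981) had 2.47 ± 1.64 TPM, Il12b, a subunit of interleukins 12 and 23 (chromosome 11, 44400063 to 44414033), had 1.32 ± 0.247 TPM, and Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), had 4.68 ± 2.21 TPM. The chemokine Ccl5 was the exception in this list with 809 ± 251 TPM, followed by Lipg (13.6 ± 5.76 TPM) and Il27 (4.87 ± 0.665 TPM).

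The early list exceeded the secondary-response list by 4.63 ± 0.78 log2 units (SD, n = 2), 5.18 in replicate 1 and 4.08 in replicate 2, above all 10000 random pairs. Both libraries gave the same sign, and an exact two-sided sign-flip test over 2 libraries cannot go below p = 0.5. The same limit holds for the other list comparisons.

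**Figure D2:**
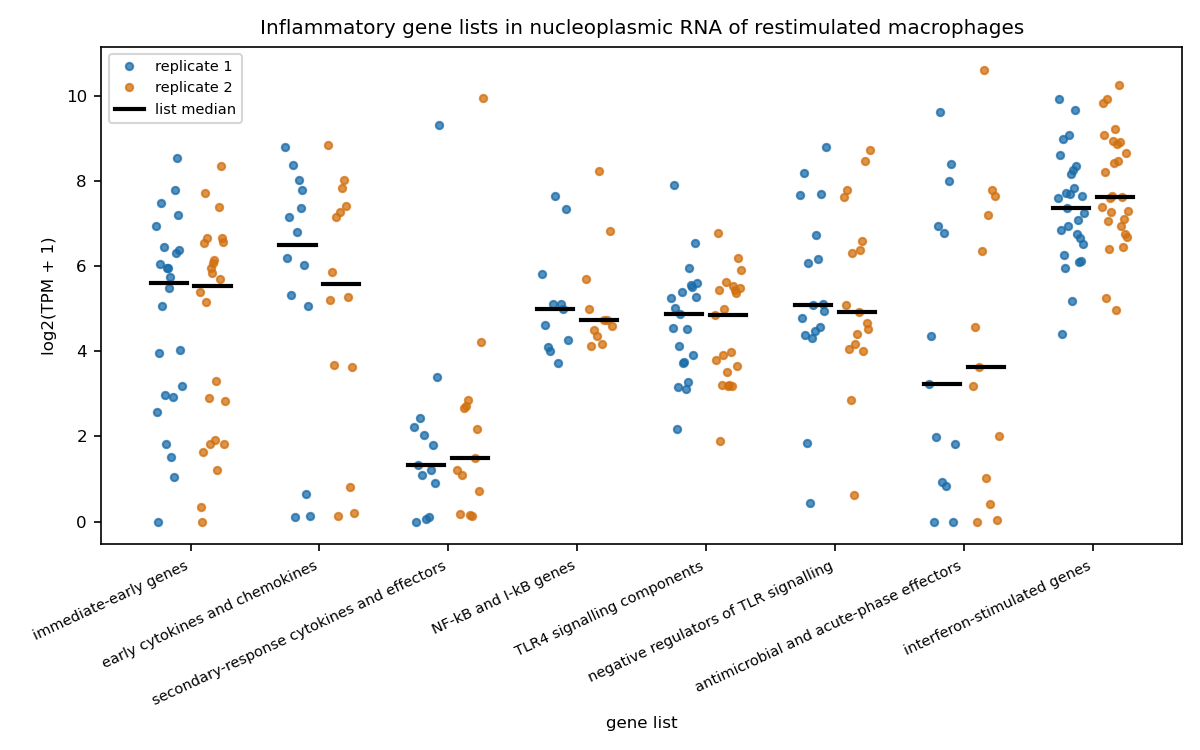
Each point is a gene of 8 inflammatory gene lists, with log2(TPM + 1) on the vertical axis, replicate 1 in blue and replicate 2 in orange, and black bars for the list median in each library. The secondary-response list has medians of 1.32 and 1.49 and the interferon-stimulated list of 7.35 and 7.62.

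Immediate-early genes, transcription factors and regulators induced within minutes of a stimulus, had a median of 47.0 ± 1.56 TPM, and 22 of 24 reached 1 TPM in both libraries. The mRNA-decay factor Zfp36 had 347 ± 30.6 TPM, Klf6 193 ± 37.7 TPM and Junb 193 ± 21.7 TPM. Egr1 (chromosome 18, 34859823 to 34864984) had 93.1 ± 9.10 TPM. Fos (chromosome 12, 85473890 to 85477273) had 121 TPM in replicate 1 and 40.7 TPM in replicate 2. Fosl2 was also lower in replicate 2, with 14.5 and 2.12 TPM. The list exceeded the secondary-response list by 4.17 ± 0.17 log2 units (SD, n = 2), above all 10000 random pairs.

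Genes of the NF-kB family and its inhibitors had a median of 28.2 ± 3.54 TPM, and all 11 reached 1 TPM. Nfkbia, which encodes the inhibitor I-kB alpha (chromosome 12, 55489410 to 55492647), had 248 ± 70.9 TPM, Nfkbiz 136 ± 33.9 TPM and Nfkb1 53.1 ± 2.97 TPM. The components of TLR4 signalling had a median of 27.9 ± 0.297 TPM. Among them the co-receptor Cd14 had 174 ± 92.4 TPM, the kinase Tbk1 81.7 ± 14.1 TPM, the transcription factor Irf5 53.2 ± 8.07 TPM, and Tlr4 itself (chromosome 4, 66827584 to 66930284) 32.5 ± 6.78 TPM.

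Negative regulators of TLR signalling were at about the level of the signalling components. Their median was 31.2 ± 2.83 TPM, and the difference of 0.15 ± 0.11 log2 units (SD, n = 2) lay at percentile 58.3 among random pairs. Acod1, the enzyme that makes itaconate, had 431 ± 15.8 TPM, Trafd1 279 ± 106 TPM and Tnip3 255 ± 51.5 TPM. Tnfaip3, which encodes the ubiquitin-editing enzyme A20 (chromosome 10, 19000910 to 19015657), had 199 ± 3.59 TPM. Irak3, which encodes IRAK-M, an inhibitory member of the IRAK family (chromosome 10, 120141648 to 120202130), had 17.8 ± 3.08 TPM. The difference was 0.08 with posterior mean TPM, 0.36 in the kallisto-layout table and 0.40 in that table rescaled to protein-coding genes, each within the range of random pairs.

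Antimicrobial and acute-phase genes were split between high and low members. Saa3, an acute-phase protein, had 790 TPM in replicate 1 and 1567 TPM in replicate 2, the lectin receptor Clec4e had 267 ± 98.2 TPM and Cybb, a subunit of the phagocyte oxidase, 238 ± 24.0 TPM, whereas 9 of 13 members reached 1 TPM in both libraries. The list median was 9.84 ± 2.11 TPM and exceeded the secondary-response list by 2.02 ± 0.16 log2 units (SD, n = 2), at percentile 98.45 among 10000 random pairs. Replicate 1 alone lay at percentile 97.45, just within the middle 95% of random pairs, and replicate 2 at 98.78. The call also ended on TMM-normalised CPM (1.43, percentile 88.5), in the kallisto-layout table (1.07, percentile 93.5) and in that table rescaled to protein-coding genes (1.76, percentile 96.8), and the difference was 3.34 over detected members.

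Interferon-stimulated genes had the highest median of the inflammatory lists, 179 ± 23.8 TPM, and all 27 members reached 1 TPM in both libraries. The antiviral gene Rsad2 had 1018 ± 294 TPM, Ifit2 934 ± 40.7 TPM and Mx1 736 ± 329 TPM. Inflammasome genes had a median of 48.0 ± 3.60 TPM, led by the pore-forming protein Gsdmd (113 ± 38.4 TPM), the DNA sensor Aim2 (95.7 ± 0.707 TPM) and Casp4 (67.4 ± 0.962 TPM). Alternative-activation genes had a median of 0.568 ± 0.0742 TPM. Tgm2 (21.4 ± 5.64 TPM) and Chil3 (2.06 ± 0.325 TPM) were the 2 of 10 above 1 TPM in both libraries, and Ccl22 had 0.890 ± 0.495 TPM.

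Glycolysis genes had a median of 34.1 ± 3.86 TPM, with Pkm at 172 TPM in replicate 1 and 129.6 TPM in replicate 2, Gapdh at 89.9 and 70.2 TPM and Aldoa at 61.6 ± 4.62 TPM. Heat-shock and stress genes had a median of 61.7 ± 7.69 TPM, with the chaperones Hspa8 at 272 ± 24.2 TPM and Hspa5 at 199 ± 33.3 TPM and Gadd45b at 158 ± 59.8 TPM. Housekeeping genes had a median of 62.1 ± 7.54 TPM, led by Actb (1594 ± 187 TPM) and B2m (884 ± 163 TPM). Proliferation genes had a median of 1.71 ± 0.194 TPM, and 8 of 14 reached 1 TPM in both libraries, with Pcna at 32.1 ± 6.85 TPM, Mki67 at 8.11 TPM in replicate 1 and 5.89 TPM in replicate 2, and Mcm2 at 4.29 ± 0.764 TPM. In both libraries 14 of the 25 lists had medians above the middle 95% of random lists of detected genes and 9 had medians below it. In 6 of these 9 no more members were detected than undetected, which by itself places the median below such random lists. The other 3 were secondary-response genes (10 of 13 members detected), proliferation genes (14 of 14) and dendritic cell markers (5 of 8).

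Between the replicates, interferon-stimulated and secondary-response genes were higher in replicate 2 than matched genes, and early cytokines and mitochondrially encoded mRNAs were lower. Interferon-stimulated genes lay 0.62 log2 units above matched random lists, higher than all 10000, with 21 of 27 members above the matched median. Of the 3 most abundant members, Mx1 and Rsad2 had log2 ratios of 0.94 and 0.60, and Ifit2 of -0.09. Secondary-response genes lay 0.52 above, at percentile 99.98, with 8 of 10 detected members above the matched median and 2 below it. Ccl5 had a log2 ratio of 0.64, Lipg of 0.83 and Nos2 of 0.81. Il6 went the other way with -1.003, and Il12b had -0.22, so the shift of the list does not hold for these cytokines. Early cytokines lay at -0.44, percentile 0.24, with 8 of 12 detected members below the matched median and 4 above it. Il1b had a log2 ratio of -1.28, Cxcl2 of -1.23, Ccl3 of -0.18 and Tnf of 0.05. On TMM-normalised CPM the list lay at -0.23 and percentile 2.78, inside the middle range, with 7 members below and 5 above, and at -0.68 in the kallisto-layout table rescaled to protein-coding genes. Secondary-response genes lay at 0.31 in the kallisto-layout table and at 0.87 in its rescaled form. Mitochondrially encoded mRNAs lay at -1.02, below all 10000, with 10 of 13 members below the matched median. Among them were mt-Atp8 at -2.31 and mt-Nd2 at -1.96. On TMM-normalised CPM, which are not divided by length, mt-Atp8 had -1.03 and mt-Nd2 -1.63. Reads of mitochondrially encoded mRNAs can be shared with their nuclear copies. The other 15 of 19 lists lay within the middle 95% of matched lists, among them immediate-early genes (0.18, percentile 93.6) and ribosomal protein mRNAs (0.07, percentile 77.3). On TMM-normalised CPM 7 lists lay outside the range rather than 4, with negative regulators (0.23), antimicrobial genes (0.40), macrophage identity genes (0.31) and ribosomal protein mRNAs (0.23) above it. Antimicrobial genes also lay above it with a pseudocount of 0.1 (percentile 97.63) and after the correction for GC content, length and level (98.26). Proliferation genes lay below it with a pseudocount of 0.1 (percentile 1.21) and in the kallisto-layout table rescaled to protein-coding genes (2.21). With 1 library per replicate these percentiles describe these 2 libraries and are no test.

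**Figure D3:**
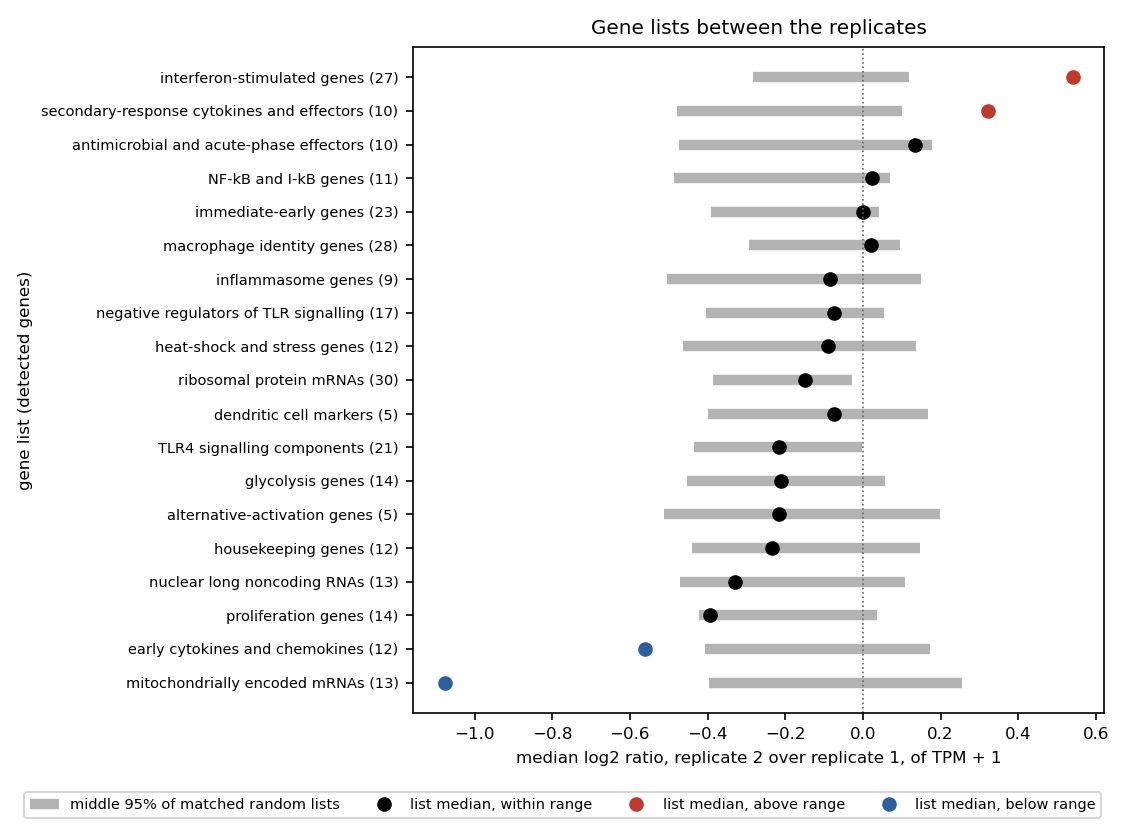
Median log2 ratio of TPM + 1, replicate 2 over replicate 1, for 19 gene lists (horizontal axis, points), with grey bars for the middle 95% of 10000 random lists matched on expression and the number of detected genes in brackets. Interferon-stimulated genes lie at 0.54, early cytokines at -0.56 and mitochondrially encoded mRNAs at -1.08.

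Among single genes with at least 100 expected counts in each library, the lowest ratios included nuclear copies of mitochondrial genes on chromosome 1. Gm28438 had a log2 ratio of -4.28 and Gm28439 of -3.06, and reads on them can be shared with the mitochondrial genome. Zfp993 (-3.08), Gm15655 (-2.35) and Fosl2 (-2.31) were also in the lowest 10, and so was Gm37376, annotated within Malat1 on the opposite strand, with 5833 TPM in replicate 1 and 1456 TPM in replicate 2. Mfsd10 was in the lowest 10 by TPM (-2.53), but its expected counts were 181 in replicate 1 and 260 in replicate 2, the opposite direction. The highest ratios belonged to the longer Rmrp model (4.76) and the ribosomal RNA gene CT010467.1 on chromosome 17 (3.33, but 0.93 for its kallisto-layout counts over library totals). Gm10382 (1.91), 4930404N11Rik (1.86), the mitochondrial ribosomal RNA mt-Rnr2 (1.84), Gm21887 (1.82), Gpsm2 (1.71), Gm16867 (1.65) and the mitochondrial ribosomal RNA mt-Rnr1 (1.60) followed. Apoe, an apolipoprotein of macrophages, had 413 TPM in replicate 1 and 1139 TPM in replicate 2, a log2 ratio of 1.46.

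Transcripts annotated with a retained intron took 20.3 ± 0.514% of the TPM of protein-coding genes outside the mitochondrial genome (SD, n = 2), and those annotated as protein-coding took 71.1 ± 0.783%. By expected counts the retained-intron share was 13.3 ± 0.389%. Among the 35 named genes of the inflammatory and nuclear noncoding lists, Tnip3 had the highest retained-intron share of TPM, 92.3 ± 1.32%. Clec4e followed with 69.8 ± 2.23%, Casp4 with 62.0 ± 4.95%, Cxcl2 with 61.0 ± 1.99% and Nfkb1 with 57.9 ± 2.90%. Tnfaip3 had 55.3 ± 5.66%. By expected counts the shares were 91.0% in Tnip3, 81.8 ± 2.07% in Clec4e, 69.2 ± 2.32% in Cxcl2, 62.7 ± 0.170% in Nfkb1, 49.9 ± 4.84% in Tnfaip3 and 41.6 ± 6.94% in Casp4. In the kallisto-layout table the mean shares of TPM were 86.2% in Tnip3, 67.1% in Casp4, 62.9% in Nfkb1 and 61.6% in Cxcl2. They were 58.5% in Clec4e, with 67.5% in replicate 1 and 49.5% in replicate 2, and 42.7% in Tnfaip3. The order below Tnip3 thus depends on the quantification. No retained-intron transcript is annotated for Tnf, Fos, Egr1 or Acod1, so their share of 0 says nothing about introns.

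The deposited tables came from 2 quantifications of each library. Gene TPM summed from the kallisto-layout table had a Spearman correlation of 0.913 in replicate 1 and 0.903 in replicate 2 with the gene table, across 12835 and 8448 genes of at least 1 TPM in both. The median log2 ratio was -0.33 in replicate 1 and -1.98 in replicate 2. In the kallisto-layout quantification, 3 genes of 57 bases annotated as microRNA (Gm24270, Gm24245 and Gm23935) and 2 processed pseudogenes (Gm12895 and Gm12896) took 38.8% of TPM in replicate 1 and 85.3% in replicate 2, while the gene table gave them 0 TPM. These 5 were singled out after their values were seen.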

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

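Entries outside the genes also carried counts. The phiX174 entry, the genome of a phage used as a sequencing control, held 56821 expected counts in replicate 1 and 12511 in replicate 2, far above the 3 counts that an observed 0 allows. Of the 26248 short entries with numeric identifiers, 3 held counts in replicate 1 and 4 in replicate 2, with 46 and 21 in the highest single entry, above the same limit. No control sample was analysed here, and no biological explanation was tested for these entries.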

How the results depend on the processing

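The kallisto-layout table rescaled to protein-coding genes and its counts as shares, and retained-intron shares of counts, were chosen after seeing the data. Except where an alternative's own construction shows it, the cause was not tested. The comparison of nuclear long noncoding RNAs with ribosomal protein mRNAs turned from -2.06 to 0.63 on TMM-normalised CPM, which leave out the division by length. On the same CPM antimicrobial minus secondary-response genes was 1.43, macrophage minus lymphocyte markers 8.19, and 7 gene lists rather than 4 lay outside matched lists between the replicates. In the kallisto-layout table early cytokines minus secondary-response genes was 3.74, immediate-early minus secondary-response genes 3.11, antimicrobial minus secondary-response genes 1.07, negative regulators minus TLR4 components 0.36, macrophage minus lymphocyte markers 5.84 and nuclear long noncoding minus ribosomal protein RNAs -0.60. Rescaled to protein-coding genes, that table gave 1.76, 0.40, 8.08 and -0.70 for the last 4 of these. TPM rescaled to protein-coding and listed genes gave 4.38 for immediate-early, 2.19 for antimicrobial and 8.10 for macrophage genes, and a pseudocount of 0.1 gave 4.74, 2.49 and 10.28. With detected members only, where fewer genes enter, these were 3.55, 3.34 and 4.64, and the noncoding comparison was -0.42. Posterior mean TPM gave 6.83 for macrophage minus lymphocyte markers. Shares of TPM moved to shares of expected counts of 74.2% for protein-coding genes, 0.102% for ribosomal protein mRNAs, 10.9% for nuclear long noncoding RNAs, 3.81% for small nuclear and ribonucleoprotein RNAs and 0.384% for snRNA, snoRNA and scaRNA genes. In the kallisto-layout table the same classes had 14.1 ± 12.4%, 0.0547 ± 0.0472%, 1.40 ± 1.51%, 7.73 ± 5.86% and 2.82 ± 1.64% of TPM (SD, n = 2), each lower in replicate 2, and 68.5%, 0.0886%, 8.48%, 2.86% and 0.353% of counts. Retained-intron transcripts had 22.6% of TPM there and 13.3% of expected counts in the transcript tables. A minimum of 100 expected counts left 9384 detected genes, the coefficient of variation without a filter was 0.282, and the Spearman correlation of the quantifications over all genes was 0.770. Leaving out either replicate only returns the value of the other library and is no further test. These values had the same sign in all 6 comparisons, from 4.08 to 5.18 for early cytokines, 4.05 to 4.29 for immediate-early, 1.90 to 2.13 for antimicrobial, 0.08 to 0.23 for negative regulators, 7.32 to 7.63 for macrophage genes and -2.35 to -1.77 for noncoding RNAs. Of the results for single lists, 122 levels moved by more than the replicate SD and 102 did not. Leaving out replicate 1 gave 24 of the unmoved levels, and leaving out replicate 2 another 24. With 2 libraries this moves a mean by less than the SD wherever the values differ, so these show no robustness. For shifts between replicates, 105 kept their call, 8 came to lie outside the matched range and 1, that of early cytokines on CPM, came to lie within it. No paired analysis was possible because the design has 1 group.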

Other observations

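Several messages in no gene list were among the most abundant of the nucleoplasm, and those named here were chosen after their values were seen. Psap, the precursor of the saposins of the lysosome, had 4469 ± 546 TPM (SD, n = 2), the highest of all protein-coding genes outside the mitochondrial genome. The class I histocompatibility genes H2-K1 and H2-D1 had 3449 ± 375 and 1964 ± 522 TPM, and the iron-storage genes Fth1 and Ftl1 had 2424 ± 429 and 1269 ± 189 TPM. The granulin precursor Grn had 1281 ± 210 TPM. The histocompatibility genes have close relatives with which reads can be shared, and so do the ferritin genes, so their values are uncertain.

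All tests of explanations were chosen after the results were seen, and no biological explanation was tested, since the design has 1 group. Interferon-stimulated genes were higher and early cytokines lower in replicate 2 than matched genes, although early cytokines came within the middle range on TMM-normalised CPM, at -0.23. After GC content, length and level were regressed out, early cytokines lay at -0.46 and interferon-stimulated genes at 0.59, both still outside the range of matched lists, which argues against those as the whole cause. More cytoplasmic mRNA in replicate 2 could raise ribosomal protein mRNAs as well. These lay at 0.0698 log2 units, with an interval of 0.00693 to 0.228 from resampled members, against 0.62 for interferon-stimulated genes. On TMM-normalised CPM they lay at 0.23, with an interval of 0.15 to 0.40, against 0.71. Such carry-over need not raise every message equally and can raise the matched genes too, so these values cannot decide whether it contributed. The starting RNA amount cannot be told apart from the replicate, with 1 library per amount, and a difference between cultures in the timing of the response stays open and untested.

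Mitochondrial ribosomal RNAs were higher in replicate 2 while 10 of 13 mitochondrially encoded mRNAs were lower on TMM-normalised CPM. Carry-over of more mitochondrial RNA would raise the mRNAs too, but their median log2 ratio was -0.70, which argues against it for the ribosomal RNAs. Less complete removal of ribosomal RNA in replicate 2 cannot be told apart from other explanations, because CT010467.1 was the single nuclear ribosomal RNA gene detected. It was higher in replicate 2 in both quantifications, though by unlike amounts. Its log2 ratio was 3.57 on that scale and 0.93 for kallisto-layout counts over library totals, or 1.17 relative to the median detected gene. For the mRNAs, adding the 7 nuclear genes that share at least 50% of their 31-base words with mitochondrial genes left the summed log2 ratio at -0.84, against -0.79 without them, which argues against a shift of reads to those copies as the whole cause. Less mitochondrial RNA carried over cannot be told apart from the other explanations for the mRNAs, because the ribosomal RNAs that would test it, with a median log2 ratio of 2.05, can also change with the removal step.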
